A study of Homo sapiens with 4 samples.

How the data were processed

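RNA sequencing data of 4 libraries from TNF-alpha-treated human umbilical vein endothelial cells were used, 2 given MoNP and 2 given MoNP-VP. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made after poly(A) enrichment. The submitters' processing notes name STAR, StringTie, DESeq2 and the genome build hg38, without versions or roles. The annotation, the counting settings, the use of strand and the handling of reads that fit several places are not given in the sources used here. The authors deposited a table of whole-number counts per gene for 48585 gene symbols, and the deposited counts were used without change. The MoNP-VP columns carry the letters VP and a replicate number. The MoNP columns are named with the word core, which the labels do not explain, and were assigned to the MoNP samples by elimination and replicate number. Every MoNP value rests on that assignment, and whether core denotes the coated particle without verteporfin was not stated. No column (0) was left without a sample, and 0 genes without a name. No count was recorded for 20644 genes in any library.

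The table names 5406 entries by another entry's symbol with a number added, for 2899 symbols. These entries held 2.81 to 3.26% of the counts per library, and 1639 of them were tested. Such copies can share reads with the entry they repeat, so those genes are uncertain, as are paralogs such as HSPA1A and HSPA1B, overlapping genes and antisense pairs. Of the symbols, 40489 matched a RefSeq symbol and 387 a synonym of 1 RefSeq gene (GRCh38, patch release 14), and 7709 matched none. Coordinates are from that annotation, are 1-based and are on the build that the submitters name hg38. Transcript lengths and GC content came from GENCODE release 29 and were found for 29077 symbols. The mitochondrial genes appear under their RefSeq symbols (such as ND1), which were matched to the list after the table was seen.

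The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), two-sided, with TMM normalisation, filterByExpr (minimum count 10, minimum total count 15), robust dispersion and group as the only term. Benjamini-Hochberg adjustment covered all 19418 genes tested, with a threshold of 0.05. The biological coefficient of variation was 17.2%. Fold changes are MoNP-VP over MoNP on the log2 scale, with a prior count of 0.125. The SE of a fold change is its absolute value divided by the square root of the F statistic. It was derived from the test, so ranges of 2 SE are approximate. Levels are TMM-normalised CPM, given as mean ± SD over 2 libraries. Before TMM scaling, a single count was worth between 0.0122 and 0.0159 CPM. Where a group had no counts, the bound was computed against a floor of 3 counts per library, which covers counting error only. Replicates within a group were separate libraries, since their counts differed by far more than sampling noise (chi-square per degree of freedom 52.2 for MoNP and 33.3 for MoNP-VP).

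Gene lists were tested with camera at a preset correlation of 0.01, two-sided, over lists with at least 5 tested members, with Benjamini-Hochberg adjustment over the 38 lists tested. Of 39 lists fixed before the data were examined, 22 were called with the preset correlation and 0 with an estimated correlation, where adjusted p ranged from 0.289 to 0.962. At the latter setting the 4 libraries leave few degrees of freedom to estimate a correlation. Lists with an estimate below 0.01 lost their call there too, so a lost call does not by itself show correlated members. The test fry called 26 lists for a change in one direction and 36 for a change in either direction. Camera compares a list's members with the other genes, whereas fry asks only whether the members change. With 43.2% of all tested genes called, fry can call lists that change no more than other genes. Counts adjusted over the list alone are printed where they differ from those over all genes. Counts of members stand against a high background. With the filter of 5 CPM in 2 libraries, 3599 of 11565 genes tested were called higher and 3564 lower. The lists cover TNF and NF-kB signalling, adhesion molecules, chemokines, interferon-stimulated genes, antigen presentation, YAP/TAZ-TEAD targets, Hippo components, endothelial identity, the KLF2/KLF4 programme, coagulation, angiogenesis, Notch, TGF-beta, matrix, cell cycle, p53, cell death, heat shock, NRF2, haem and iron, the unfolded protein response, ATF4, cholesterol, autophagy, hypoxia, oxidative phosphorylation, immediate early genes, aryl hydrocarbon receptor targets, actin, other cell types, mitochondrial, ribosomal and histone genes.

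The rule for named genes was also fixed before the data were examined. Per direction it took the 10 genes with the largest absolute log2 fold change among those called, with groups that did not overlap, a mean of at least 5 CPM in the higher group and a standard symbol. To these it added the 5 per direction with the smallest p, a fixed panel of 25 inflammatory, YAP pathway, endothelial, stress and monocyte genes, and up to 4 members per list with the smallest p. Of the panel, 23 genes were tested and 21 called. Levels of sex-linked marker genes were not reported. Some genes that the rule took are not reported here.

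The procedure was tested on simulated counts drawn from the real means and library sizes for the comparison of MoNP-VP with MoNP, with 18673 genes tested. Changes of 1 or 2 on the log2 scale were given to 200 genes and a change of 0.8 to a list of 25 others, and 222 of these were tested. The 200 genes were drawn from those at a mean of at least 5 CPM. The procedure called 88.9% of genes changed by 1 and 99% of those changed by 2 on the log2 scale. These shares do not cover genes at lower counts. Of 225 calls, 200 were true and 25 (11.1%) were false, among 18451 unchanged genes. That was above the 5% intended, in a setting where few genes change. None of 20 unchanged lists was called (0), and the changed list was found. Genes were drawn independently, so the simulated lists lack the correlation between members of real lists. Their result does not measure how many list calls are false in the real data.

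Alternatives fixed in advance were RLE and upper-quartile factors, library size alone, DESeq2 1.42.0, limma voom, no filter beyond 1 count, a filter of 5 CPM in 2 libraries, the replicate number as a block, leaving out each library, a threshold of 1 on the absolute log2 fold change, camera with an estimated correlation, fry, and list members at a mean of 5 CPM or more. Summing numbered copies into their symbol was added after seeing the data. Pseudocount alternatives apply to normalised values only and were not run. Figures were drawn with matplotlib 3.10.9.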

Results

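Gene expression was measured by RNA sequencing of polyadenylated RNA in human umbilical vein endothelial cells (HUVEC), the cells that line the vein of the umbilical cord. All cells were treated with TNF-alpha, a cytokine that switches on inflammatory genes in endothelium. One group received nanoparticles coated with monocyte membrane (MoNP), and the other received the same kind of particle with verteporfin (MoNP-VP). Verteporfin is a porphyrin used as a photosensitiser and as an inhibitor of the binding of YAP to TEAD transcription factors. Each group held 2 libraries. The total count was 78879228 and 81902305 in the MoNP libraries and 62700758 and 71496597 in the MoNP-VP libraries. The labels name replicates but do not say that they came from separate cultures or donors. The p-values thus measure the spread between these libraries, whatever its source. Each gene's spread was estimated with information shared across the genes tested (median total degrees of freedom 7.16). No library came from cells without TNF-alpha or without particles. The labels give neither the dose and duration of TNF-alpha and particles nor whether light was applied.

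The comparison asks how loading the particle with verteporfin changed the transcriptome of TNF-alpha-treated endothelial cells. With MoNP-VP, 13 of 16 leukocyte adhesion molecules and 24 of 29 chemokines and cytokines fell, while 29 of 31 genes of the ATF4 response, 17 of 28 of the unfolded protein response and 20 of 27 heat shock genes rose. In the other direction, 2 adhesion molecules and 4 chemokines and cytokines rose and 7 unfolded protein response genes fell. These lists were called by camera with a preset correlation but not with an estimated correlation, where the adjusted p was 0.289 for the ATF4 list, 0.410 for heat shock and 0.319 for the others. VCAM1, which binds leukocytes to inflamed endothelium, went from 3953 ± 42.3 CPM (counts scaled to library size, with TMM normalisation; SD, n = 2) with MoNP to 18.0 ± 11.3 with MoNP-VP. HMOX1, which encodes a haem oxygenase, went from 53.6 ± 11.01 to 1699 ± 234 CPM. Of 19418 genes tested, 8385 (43.2%) were called at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 4171 were higher and 4214 were lower with MoNP-VP, and 1591 and 1750 of them differed by at least 1 on the log2 scale. The called genes included 7096 protein-coding genes and 494 long non-coding RNAs. The groups did not overlap for 14172 genes (73.0%), where chance gives 33.3%. The table holds 5406 entries that repeat another entry's symbol with a number added, and 518 of these were among the called genes. With such entries summed into their symbol, an alternative chosen after seeing the data, 7896 genes were called.

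Inflammatory genes. Of the 25 members of the TNF and NF-kB list, 23 fell and 2 rose, with a median log2 fold change of -1.51 (camera, adjusted p = 1.60e-16; adjusted p = 0.319 with an estimated correlation). Chemokines and cytokines fell in 24 of 29 tested members and rose in 4, with a median of -1.998 (adjusted p = 1.89e-11; adjusted p = 0.319 with an estimated correlation). Leukocyte adhesion molecules fell in 13 of 16 and rose in 2, with a median of -1.75 (adjusted p = 1.18e-05; adjusted p = 0.319 with an estimated correlation). E-selectin (SELE), which makes leukocytes roll on the vessel wall, fell from 9047 ± 130 to 151 ± 86.5 CPM, a log2 fold change of -5.90 (SE 0.66, edgeR adjusted p = 0.0159). ICAM1, a ligand of leukocyte integrins, fell from 2954 ± 167 to 254.5 ± 106 CPM (log2 -3.54, SE 0.39, adjusted p = 0.00820). VCAM1, at chromosome 1, 100719742 to 100739045 (GRCh38), changed by -7.78 (SE 0.77, adjusted p = 0.0122). CX3CL1, a membrane-bound chemokine, changed by -8.25 (SE 0.85, adjusted p = 0.0133), and CCL2, the monocyte attractant, by -4.13 (SE 0.48, adjusted p = 0.0119). The NF-kB feedback inhibitors TNFAIP3 and NFKBIA changed by -2.58 and -0.96 on the log2 scale. CXCL8, the neutrophil attractant, changed by -1.41 (SE 0.17, adjusted p = 0.00125) and stood at 977 ± 253 CPM with MoNP-VP. Other members with small p were SOD2, the mitochondrial superoxide dismutase (log2 -4.997), RIPK2 (-2.19), CD83 (-4.02), TNFSF10, which encodes TRAIL (-5.10), CSF1 (-2.32), CXCL6 (-3.26), IL32 (-1.33), F11R (-1.63) and SELP (-3.15). IL6 went the other way, from 100 ± 12.3 to 146 ± 34.7 CPM (log2 0.55, SE 0.17, adjusted p = 0.0463). The IL6 call was lost without MoNP replicate 1 (log2 0.43, adjusted p = 0.272), without MoNP replicate 2 (0.68, 0.1248) and without MoNP-VP replicate 1 (0.29, 0.0822). It was also lost with DESeq2 (0.0902), voom (0.0659), the replicate block (0.118), no filter (0.0796), the filter at 5 CPM (0.0791) and numbered copies summed (0.0693), with a range of 0.000540 to 0.272 over the alternatives.

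The MoNP-VP libraries differed from each other for these genes, which widened the errors. Without MoNP replicate 1, the log2 fold changes stayed near the full values but the calls were lost for VCAM1 (-7.77, adjusted p = 0.0909), SELE (-5.92, 0.0957), ICAM1 (-3.59, 0.0699), CCL2 (-4.08, 0.0830) and CX3CL1 (-8.29, 0.114). Without MoNP replicate 2 they were lost as well, with VCAM1 at -7.79 (0.0876), SELE at -5.89 (0.0986), ICAM1 at -3.48 (0.0791), CCL2 at -4.18 (0.0959) and CX3CL1 at -8.20 (0.112). Without MoNP-VP replicate 1, the log2 fold changes became -8.62 for VCAM1, -6.65 for SELE, -4.74 for CCL2 and -10.01 for CX3CL1. Without MoNP-VP replicate 2, CX3CL1 became -7.42. Over the 13 alternatives the highest adjusted p was 0.0909 for VCAM1, 0.0986 for SELE, 0.0791 for ICAM1, 0.0959 for CCL2 and 0.114 for CX3CL1, and the lowest were 7.49e-33, 4.44e-23, 8.38e-16, 8.83e-16 and 2.02e-14.

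**Figure D1:**
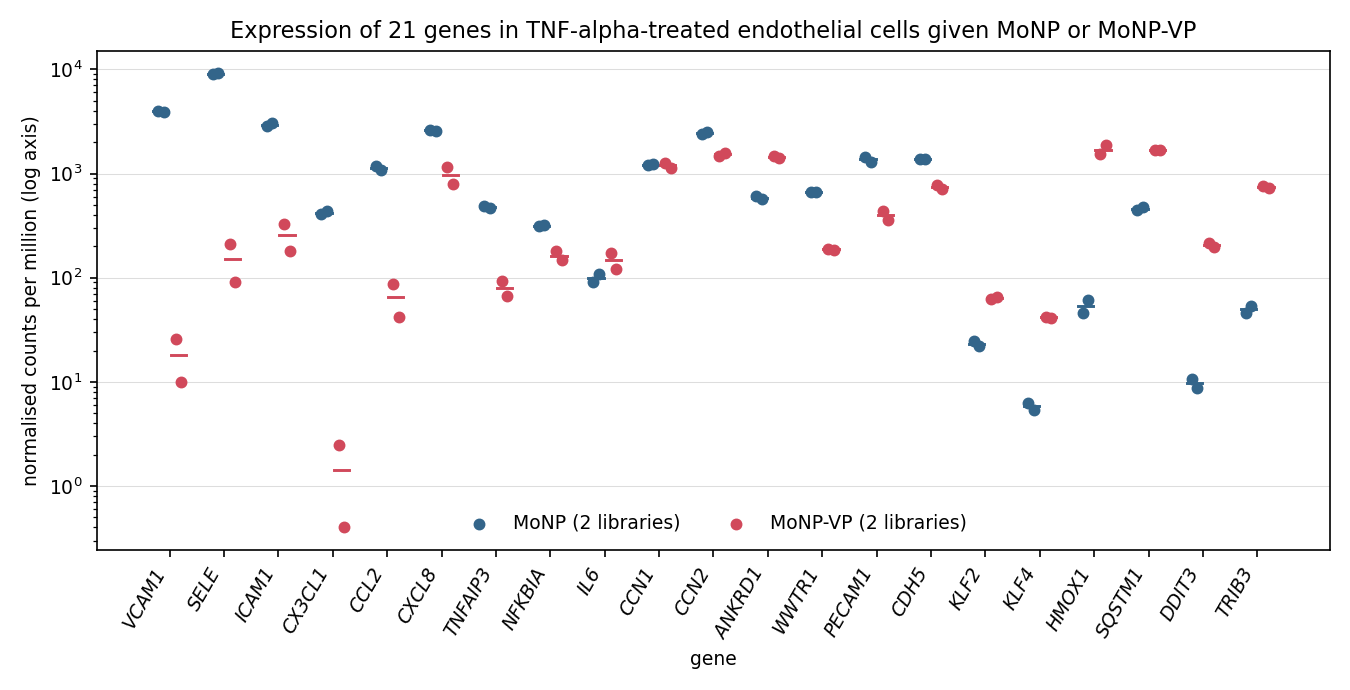
Normalised CPM (log axis) of 21 genes in each library, with points for libraries, short lines for group means, blue for MoNP and red for MoNP-VP (2 libraries per group). VCAM1, SELE, ICAM1, CX3CL1 and CCL2 lie far lower with MoNP-VP, HMOX1, DDIT3 and TRIB3 lie higher, and CCN1 has overlapping groups.

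Interferon-stimulated genes and antigen presentation. Of 41 interferon-stimulated genes, 32 fell and 1 rose (33 and 1 adjusted over the list alone), with a median of -1.15 (camera, adjusted p = 2.76e-12; adjusted p = 0.319 with an estimated correlation). GBP4, a guanylate-binding protein, changed by -5.15, GBP2 by -2.52, GBP1 by -2.18 and PARP14 by -2.08. Of 17 antigen presentation genes, 14 fell and none rose (16 fell adjusted over the list alone), with a median of -1.04 (adjusted p = 1.47e-07; adjusted p = 0.289 with an estimated correlation). The peptide-trimming enzymes ERAP1 and ERAP2 changed by -1.43 and -1.37, the peptide-loading factor TAPBP by -1.59 and HLA-E by -0.96. For 11 of these 17 genes the table holds numbered copies that can share reads, so the level of any single entry is uncertain. Summed over their copies, HLA-B changed by -1.13 (SE 0.07), HLA-E by -0.95 (SE 0.06) and B2M, the invariant chain of class I molecules, by -0.88 (SE 0.07). HLA-B and B2M were chosen after their values were seen.

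YAP/TAZ-TEAD targets and the Hippo pathway. The list of YAP/TAZ-TEAD targets was not called, since 14 of 30 tested members rose and 12 fell (16 and 12 adjusted over the list alone). Its median log2 fold change was 0.21, its mean was -0.23 and camera's direction was down (adjusted p = 0.394). The test fry asks whether the members move one way on balance, without comparing them with other genes. It gave an adjusted p of 0.0294, also down, and the range over the alternatives was 0.0294 to 0.992. CCN1, a widely used YAP target, stood at 1216 ± 15.4 CPM with MoNP and 1195 ± 79.4 with MoNP-VP (log2 -0.02, SE 0.07, edgeR adjusted p = 0.813). CCN2 fell (log2 -0.68, SE 0.07), ANKRD1 rose (1.29, SE 0.07) and AMOTL2 rose (0.27, SE 0.06). The members with the smallest p were CAVIN2, a caveolar coat protein (-3.19), the tissue factor gene F3 (-4.12), ANGPT2 (-1.73) and the stress gene GADD45B (1.70). Among the pathway's own genes, WWTR1, which encodes TAZ, went from 670 ± 2.42 to 187 ± 4.49 CPM (log2 -1.84, SE 0.06, adjusted p = 2.08e-06). YAP1 changed by -0.37 (SE 0.07, adjusted p = 0.00609) and TEAD1 by 0.67 (SE 0.08). The 19 Hippo components, of which 8 rose and 7 fell, were not called as a list (adjusted p = 0.0972), but were with fry (0.0165) and DESeq2 (0.0410), with a range of 0.0165 to 0.798 over the alternatives. VGLL4, a TEAD cofactor (-1.73), SAV1, a scaffold of the Hippo kinases (-1.58), and TEAD2 (-0.75) fell.

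Endothelial genes. Of 28 endothelial identity genes, 23 fell and 4 rose, with a median of -0.88 (camera, adjusted p = 1.32e-16; adjusted p = 0.289 with an estimated correlation). Von Willebrand factor (VWF), which tethers platelets, went from 4157 ± 157 to 371 ± 48.1 CPM (log2 -3.49, SE 0.10, edgeR adjusted p = 1.36e-06). The junctional adhesion molecule PECAM1 changed by -1.80 (SE 0.11) and VE-cadherin (CDH5) by -0.88 (SE 0.07). MMRN1 (-3.59), LYVE1 (-3.17) and EMCN (-2.46) fell as well. Coagulation and fibrinolysis genes fell in 12 of 18 and rose in 2 (median -0.77, adjusted p = 2.08e-09; adjusted p = 0.289 with an estimated correlation), among them TFPI2, a serine protease inhibitor (-3.40), and F3 (-4.12). Angiogenesis and tip cell genes fell in 17 of 26 and rose in 7 (18 and 7 adjusted over the list alone; median -0.78, adjusted p = 0.0197; adjusted p = 0.319 with an estimated correlation). ANGPT2, VEGFC (-1.44) and MMP2 (-1.77) fell in that list, and PGF, the placental growth factor, rose (2.60). Notch signalling genes fell in 6 of 17 and rose in 3 (7 and 3 adjusted over the list alone; median -0.28, adjusted p = 0.0223; adjusted p = 0.319 with an estimated correlation), with EFNB2 at -2.45, JAG1 at -1.31, NRARP at -1.31 and GJA4 at -4.98. The call of the Notch list was lost without MoNP-VP replicate 1 (median -0.30, adjusted p = 0.0739), without MoNP-VP replicate 2 (-0.55, 0.153) and with voom (-0.23, 0.134). With only genes at 5 CPM or more in 2 libraries tested, the angiogenesis list (0.0859) and the Notch list (0.0952) were not called. Over the alternatives the range was 0.00103 to 0.319 for angiogenesis and 0.0103 to 0.319 for Notch. In the list of the KLF2/KLF4 and nitric oxide programme, 5 of 17 rose and 6 fell (median 0.03, mean -0.87, camera's direction down, adjusted p = 0.924). KLF2 and KLF4, transcription factors of the flow response, rose by 1.44 (SE 0.09) and 2.82 (SE 0.12), while the nitric oxide synthase gene NOS3 stood at 22.1 ± 1.05 and 22.5 ± 0.134 CPM (log2 0.03, SE 0.10, adjusted p = 0.834). CAV1 (-1.84) and SLC7A2 (-1.79), also in that list, fell.

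Matrix and mesenchymal genes. Extracellular matrix genes fell in 29 of 34 and rose in 1, with a median of -1.76 (camera, adjusted p = 1.16e-31; adjusted p = 0.289 with an estimated correlation). Perlecan (HSPG2), a basement membrane proteoglycan, went from 11269 ± 343 to 1151 ± 133 CPM (log2 -3.29, SE 0.09), fibrillin (FBN1) changed by -3.01 and periostin (POSTN) by -4.51. Of 10 tested fibroblast markers, 6 fell and none rose (median -2.36, adjusted p = 6.28e-06; adjusted p = 0.289 with an estimated correlation), with COL1A2 at -3.02, COL3A1 at -3.37 and PDGFRA at -3.85 (-4.55 without MoNP-VP replicate 2). The list of TGF-beta and mesenchymal transition was not called (10 of 28 rose and 9 fell, 13 and 10 adjusted over the list alone; median 0.19, mean -0.10, camera's direction up, adjusted p = 0.924). Its members moved far in both directions. SMAD7, an inhibitor of TGF-beta signalling, rose by 4.01, and SNAI1, a repressor of cadherin genes, by 3.21. BMP4 (-3.73) and fibronectin (FN1, -1.58) fell.

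Stress responses. Of 31 tested genes of the ATF4 and amino acid response, 29 rose and none fell (29 and 1 adjusted over the list alone), with a median of 1.61 (camera, adjusted p = 1.32e-47; adjusted p = 0.289 with an estimated correlation). DDIT3, the stress transcription factor also called CHOP, at chromosome 12, 57516588 to 57520517 (GRCh38), went from 9.69 ± 1.48 to 207 ± 10.8 CPM (log2 4.42, SE 0.12, edgeR adjusted p = 1.07e-06). Its span overlaps MARS1, which was also called higher and was chosen after its value was seen. TRIB3, a pseudokinase, rose by 3.89, GDF15, a secreted stress cytokine, by 3.16 and CEBPB by 2.75. Of 28 genes of the unfolded protein response, 17 rose and 7 fell (18 and 8 adjusted over the list alone; median 1.05, adjusted p = 7.66e-17; adjusted p = 0.319 with an estimated correlation). ATF3 rose by 3.83, DNAJB9, a chaperone of the endoplasmic reticulum, by 3.76, and HERPUD1, a factor of endoplasmic reticulum degradation, by 3.80. Heat shock genes rose in 20 of 27 and fell in none (21 rose adjusted over the list alone; median 0.88, adjusted p = 2.08e-09; adjusted p = 0.410 with an estimated correlation), including BAG3 (1.55) and HSPD1 (1.17). NRF2 and oxidative stress genes rose in 17 of 32 and fell in 5 (median 0.31, adjusted p = 1.74e-05; adjusted p = 0.319 with an estimated correlation). OSGIN1 (3.30), SRXN1 (2.54) and thioredoxin reductase (TXNRD1, 2.12) rose in that list and SOD2 fell. SQSTM1, an autophagy receptor and NRF2 target, rose from 461 ± 22.6 to 1687 ± 18.8 CPM (log2 1.87, SE 0.07). The list of haem, porphyrin and iron genes was not called (4 of 24 rose and 9 fell, median -0.02, adjusted p = 0.394), but was with fry (0.0482; range 0.0482 to 0.897 over the alternatives). HMOX1 (4.99) and the ferritin light chain FTL (0.84) rose in it, and the iron exporter SLC40A1 (-4.55) and the haem synthesis enzyme ALAD (-0.97) fell. Hypoxia and glycolysis genes rose in 17 of 34 and fell in 6 (median 0.27, adjusted p = 0.00226; adjusted p = 0.294 with an estimated correlation), with SLC2A3, a glucose transporter, at 1.89, BHLHE40 at 1.58, NDRG1 at 1.497 and KDM3A at 1.23.

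The p53 targets rose in 9 of 27 and fell in 6 (11 and 6 adjusted over the list alone; median 0.16, camera adjusted p = 0.0253; adjusted p = 0.490 with an estimated correlation). SESN2 (2.83) and GADD45A (2.33), which ATF4 also induces, and GDF15 rose in that list, while BTG2 fell (-1.67). Aryl hydrocarbon receptor targets rose in 4 of 9 and fell in none (4 and 1 adjusted over the list alone; median 0.48, adjusted p = 0.0297; adjusted p = 0.506 with an estimated correlation), with TIPARP at 1.77, NQO1 at 0.97, CYP1A1 at 0.95 and NFE2L2 at 0.56. The p53 call was lost without MoNP replicate 1 (0.0651), without MoNP-VP replicate 1 (0.184), without MoNP-VP replicate 2 (0.0677), with voom (0.134), with no filter (0.0864) and with the filter at 5 CPM (0.0859), with a range of 0.00251 to 0.490 over the alternatives. The aryl hydrocarbon receptor call was lost without MoNP replicate 2 (median 0.28, adjusted p = 0.0517), without MoNP-VP replicate 1 (0.75, 0.0502), without MoNP-VP replicate 2 (0.13, 0.120), with voom (0.108) and with the filter at 5 CPM (0.0779), with a range of 0.0117 to 0.506 over the alternatives.

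Cell cycle, death and metabolism. S phase and DNA replication genes rose in 20 of 40 and fell in 2 (median 0.36, camera adjusted p = 0.000335; adjusted p = 0.289 with an estimated correlation). The replication licensing factors CDC6 (3.25), CDT1 (1.52) and MCM7 (0.87) and the helicase cofactor CDC45 (1.52) rose. The G2/M and mitosis list was not called (12 of 40 rose and 5 fell, 13 and 5 adjusted over the list alone; median 0.11, adjusted p = 0.223), with MYBL2 at 0.86, BUB3 at 0.63, KIF2C at 0.84 and UBE2C at 0.70. Replication-dependent histone genes rose in 6 of 14 and fell in none (median 1.54, adjusted p = 0.0773), with H2AC6 at 2.21, H2BC4 at 1.92, H2BC8 at 3.32 and H2BC5 at 1.38. The histone list was called without MoNP replicate 1 (0.0352), without MoNP-VP replicate 1 (0.0186), without MoNP-VP replicate 2 (median 0.99, adjusted p = 0.0481), with no filter (0.00428), with voom (0.0218) and with fry (0.0263), with a range of 0.00428 to 0.392 over the alternatives. Cell death regulators rose in 8 of 28 and fell in 6 (9 and 7 adjusted over the list alone; median 0.00, mean -0.11, adjusted p = 0.924). The anti-apoptotic NF-kB targets CFLAR (-1.18), BCL2A1 (-3.51) and BIRC3 (-1.41) fell in it. Immediate early genes rose in 11 of 28 and fell in 12 (median 0.02, mean -0.53, adjusted p = 0.924), with EGR1 at -3.20, NR4A3 at -4.51 and the phosphatase gene DUSP1 at 1.97. Actin cytoskeleton and SRF targets rose in 9 of 32 and fell in 13 (11 and 13 adjusted over the list alone; median -0.12, adjusted p = 0.595), with FHL2 at 1.83, MYH10 at -1.60, ITGB1 at -1.09 and CNN3 at -0.94.

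Nuclear genes of oxidative phosphorylation fell in 16 of 36 and rose in 1 (16 and 2 adjusted over the list alone; median -0.16, camera adjusted p = 0.0462; adjusted p = 0.392 with an estimated correlation). NDUFV2 (-0.77), NDUFA4 (-0.77), SDHC (-0.66) and NDUFB3 (-0.88) fell. That list's call was lost without MoNP replicate 2 (0.0778), with RLE factors (0.0537), with library size alone (0.111), with DESeq2 (0.0541), with the filter at 5 CPM (0.139) and with numbered copies summed (0.0502), with a range of 0.000709 to 0.392 over the alternatives. The mitochondrially encoded messenger RNAs fell in 11 of 13 and rose in none (12 fell adjusted over the list alone; median -0.96, adjusted p = 0.0103; adjusted p = 0.687 with an estimated correlation), with ND3 at -0.77, COX3 at -1.06, ATP6 at -1.07 and ND1 at -0.76. Their call was lost with fry (0.116) and with the filter at 5 CPM (0.0859), with a range of 1.54e-09 to 0.687 over the alternatives. With voom the calls of ATP6 (0.0614, range 5.32e-05 to 0.0614) and ND1 (0.0509, range 0.000123 to 0.0509) were lost. Their share of all counts was 3.17 ± 0.656% with MoNP and 1.78 ± 0.349% with MoNP-VP (SD, n = 2). Autophagy and lysosome genes rose in 16 of 37 and fell in 11 (16 and 12 adjusted over the list alone; median 0.14, adjusted p = 0.223; fry 0.0316, range 0.0316 to 0.414 over the alternatives), with FNIP1 at 1.75, GABARAPL1 at 1.56 and MAP1LC3B at 1.08. Cholesterol synthesis and uptake genes rose in 8 of 33 and fell in 6 (median -0.03, camera's direction up, adjusted p = 0.794), with STARD4 at 1.501 and SREBF1 at 0.66. Cholesterol efflux and LXR targets rose in 2 of 12 and fell in 6 (median -0.36, adjusted p = 0.924). The lysosomal cholesterol exporter NPC1 (1.84) and ABCA1 (0.46) rose, and ABCG1 (-1.11) and NPC2 (-0.53) fell. Of 50 cytosolic ribosomal protein genes, RPL10A rose (0.22) and RPS28 fell (-0.24), and neither passed when adjusted over the list alone. RPL10A was not called without MoNP replicate 2 (adjusted p = 0.1404), MoNP-VP replicate 1 (0.109) or MoNP-VP replicate 2 (0.111), with a range of 0.00205 to 0.1404. RPS28 was not called without MoNP replicate 1 (0.0723), MoNP-VP replicate 1 (0.0666) or MoNP-VP replicate 2 (0.0833) or with library size alone (-0.16, 0.0601), with a range of 0.00101 to 0.0833. The ribosomal median was -0.00 and its sign turned with the scaling, to 0.01 with RLE factors and 0.08 with library size alone.

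Markers of other cell types. Of 31 monocyte and macrophage markers, 10 passed the count filter, of which 2 rose and 3 fell (median -0.35, mean 0.73, camera's direction down, adjusted p = 0.748). CD14 had 9, 15, 8 and 6 counts in the libraries in the order MoNP 1 and 2, then MoNP-VP 1 and 2, and PTPRC, which all leukocytes carry, had 0, 0, 8 and 0. LAPTM5 (-0.54) and VCAN (-1.22) fell, and FCGR2A, under 1 CPM in every library, was called lower but not without MoNP replicate 1 (0.115) or MoNP replicate 2 (0.0797; range 0.00477 to 0.115). Its log2 fold change was -4.31, and -3.41 without MoNP-VP replicate 1 and -8.44 without MoNP-VP replicate 2. FCGR1A, with no counts with MoNP and 32 and 10 with MoNP-VP, was called higher (adjusted p = 0.0229), at least 8.26-fold, at least 3.52-fold without MoNP-VP replicate 1 and at least 13.0-fold without MoNP-VP replicate 2. The FCGR1A call was lost without MoNP replicate 1 (0.0783), without MoNP replicate 2 (0.0829) and with the replicate block (0.0613), with a range of 0.00462 to 0.0829. Epithelial markers rose in 5 of 8 tested members and fell in none (5 and 1 adjusted over the list alone; median 0.69, adjusted p = 0.0311; adjusted p = 0.319 with an estimated correlation). The keratins KRT19 (1.14), KRT18 (0.67) and KRT7 (0.72) rose. The epithelial call was lost without MoNP replicate 2 (0.0517; range 0.0141 to 0.319 over the alternatives). Smooth muscle and pericyte markers rose in 1 of 10 and fell in 4 (4 and 4 adjusted over the list alone; median -0.05, mean 0.15, camera's direction down, adjusted p = 0.794), with MCAM, also an endothelial protein, at -1.05, RGS5 at -0.50, NOTCH3 at -0.79 and SMTN at 0.37. NOTCH3 was not called without MoNP replicate 2 (-0.69, adjusted p = 0.0958) or MoNP-VP replicate 1 (-0.58, 0.0600), with a range of 0.00625 to 0.0958. Of 20 lymphocyte and red cell markers, 2 were tested, CD79A (adjusted p = 0.103) and CD79B (adjusted p = 0.352), too few for a list test.

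**Figure D2:**
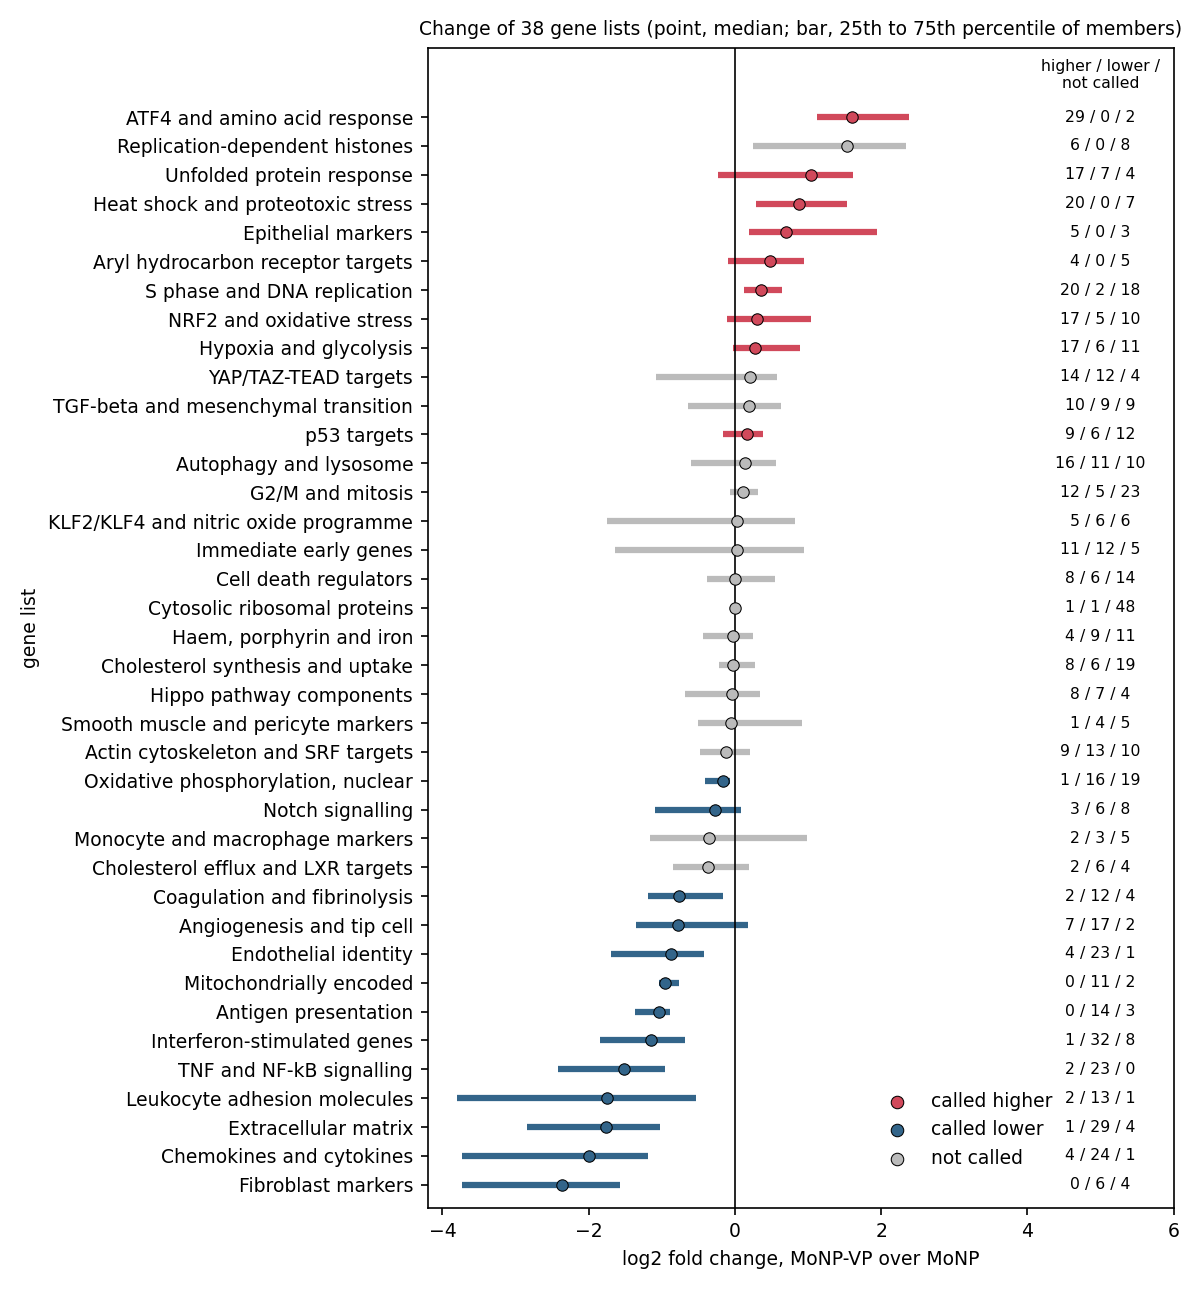
Median log2 fold change (MoNP-VP over MoNP) of the 38 gene lists tested, with bars from the 25th to the 75th percentile of members and the number of members higher, lower and not called at the right. Red lists were called higher, blue lists lower and grey lists were not called by camera with a preset correlation; 9 lists were called higher and 13 lower.

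Genes with the largest and the most certain changes. The smallest p among higher genes not named by size belonged to E2F7, a cell cycle repressor (30.4 ± 1.16 to 376 ± 6.07 CPM, log2 3.63), ATF3, DNAJB9, TRIB3 and GPRC5A (2.70). Among lower genes they belonged to GIMAP8 (206 ± 2.26 to 3.18 ± 0.106 CPM, log2 -6.01), GIMAP6 (-4.29), TFPI2, MMRN1 and SLC40A1. GIMAP8 and GIMAP6 encode GTPases of the immunity-associated family on chromosome 7. The largest rises among genes at 5 CPM or more in the higher group included GEM, a small GTPase (log2 5.32, SE 0.32), BHLHA15 (5.18, SE 0.16), HMOX1, DDIT3, ERFE (4.35, SE 0.25) and the cytokine IL11 (4.18, SE 0.24). GEM changed by 6.05 without MoNP replicate 2. The pseudogene RPLP0P2 changed by 7.91, by 6.98 without MoNP replicate 1 and by 11.88 without MoNP replicate 2. HSPA6, an inducible chaperone, stood at 0.102 ± 0.00268 and 8.52 ± 7.21 CPM (log2 6.36, SE 0.95). It changed by 7.03 without MoNP-VP replicate 1 and by 5.04 without MoNP-VP replicate 2, and its call was lost without MoNP replicate 1 (0.146), without MoNP replicate 2 (0.144) and with voom (0.280), with a range of 2.86e-09 to 0.280 over the alternatives. HIF1A-AS3 changed by 4.86, by 6.27 without MoNP replicate 1 and by 4.15 without MoNP replicate 2. It lies antisense to HIF1A, which changed by -0.49, and reads of the pair cannot be told apart without strand. The span of HIF1A-AS3 also overlaps HIF1A-AS2, which changed by 4.62 (15 and 14 counts with MoNP, 176 and 478 with MoNP-VP). C8orf44-SGK3, a read-through transcript, had no counts with MoNP and 5.92 ± 3.12 CPM with MoNP-VP, at least 154-fold higher against a floor of 3 counts per library, and at least 96.8-fold higher without MoNP-VP replicate 2. It shares its sequence with SGK3, which was not called (log2 -0.32, adjusted p = 0.187).

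The largest falls included CX3CL1 and DEPP1, a FOXO target (196 ± 12.6 to 0.885 ± 0.449 CPM, log2 -7.81, and -8.42 without MoNP-VP replicate 1). ADIRF (6.17 ± 2.07 CPM with MoNP) and GIMAP5 (5.90 ± 0.651) had no counts with MoNP-VP, so they were at least 141-fold and 135-fold lower. Both overlap other annotated transcripts that were detected with MoNP-VP. The read-through transcript GIMAP1-GIMAP5 had 12 counts in each MoNP-VP library and none with MoNP, and ADIRF-AS1 had a log2 fold change of 2.78 (adjusted p = 0.0851). Reads of such overlapping genes are not told apart by the counts. The other 6 places were taken by OR2I1P and its numbered copies, all without counts in MoNP-VP. OR2I1P, at chromosome 6, 29550407 to 29557773 (GRCh38), stood at 8.50 ± 0.465 CPM with MoNP and was at least 195-fold lower with MoNP-VP. Its span overlaps UBD, which is induced by TNF-alpha and had 0 counts in all 4 libraries, so the gene behind these reads is uncertain. UBD, GIMAP1-GIMAP5, ADIRF-AS1, SGK3, HIF1A and HIF1A-AS2 were chosen after their values were seen.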

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

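Summing numbered copies was the only alternative here chosen after seeing the data. No named gene and no list reversed its direction under any setting in which either value was called, and 184 of 203 genes carried through the alternatives kept their side of the threshold under each setting in which they were tested. The filter at 5 CPM and the summing of copies left some of these genes untested, and settings at 5 CPM some lists. Of 38 lists, 11 changed under no setting that tested them and 15 only with an estimated correlation. The count of called genes (8385) lay between 7163 and 8645 across the normalisations, tests and filters, and at 7896 with numbered copies summed. With library size alone, 57.2% of calls were higher against 49.7%, and the median of all genes moved from -0.01 to 0.08. A threshold of 1 on the absolute log2 fold change left 3341 genes, 1591 higher and 1750 lower, as the stricter criterion itself removes genes. Of the gene lists, 22 were called, 14 with the filter at 5 CPM (fewer genes tested), 0 with an estimated correlation, 26 with fry and 20 with members at 5 CPM or more. With an estimated correlation, lists whose estimate lay below the preset 0.01 lost their call too. Among them were coagulation (-0.00980) and fibroblast markers (-0.107), so a higher correlation cannot be the cause for them.

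Leaving out 1 library at a time leaves a group with a single library, which is assumed to vary like the other group. The calls then numbered 6397 to 7020 genes (3298 to 3388 higher, 3099 to 3671 lower), 19 to 22 lists and 15 to 21 of the panel's 21 called genes. The replicate numbers do not pair the libraries as far as the data show, since deviations of same-numbered libraries had a correlation across genes of -0.0036. With the replicate block, 7908 genes were called (3867 higher, 4041 lower), with 22 lists and 19 panel genes. Under the block CX3CL1 (adjusted p = 0.0605) and IL6 (0.118) were not called. Depth limits statements on genes near the floor of 0.0366 to 0.0478 CPM (before TMM scaling) that 3 counts allow.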

Other observations

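The test of the immediate early list, the test of other cell types and the carry-over test were chosen after the data were seen. So were the scan of gene families, the comparison of mitochondrial transcript classes and the comparison of the MoNP-VP libraries with random lists. The carry-over test was rewritten after a first version had left the matter undecided, and the criterion of the immediate early test was revised several times after its result was seen. The tests of transcript length and GC content and of the TNF receptor were fixed before their results.

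Mitochondrial transcripts moved apart by class. While 11 of the 13 mitochondrially encoded messenger RNAs fell with MoNP-VP, both mitochondrial ribosomal RNAs rose in the same libraries. RNR1, the small subunit RNA, went from 594 ± 51.9 to 1562 ± 39.5 CPM (SD, n = 2; log2 1.396, SE 0.08, edgeR adjusted p = 1.43e-05), and RNR2 from 6121 ± 812 to 8392 ± 538 CPM (0.46, SE 0.10, adjusted p = 0.00793). Their joint share of counts was 0.712% and 0.593% in the MoNP libraries and 1.06% and 0.988% in the MoNP-VP libraries. The libraries were enriched for poly(A), so the levels depend on how these RNAs are tailed and captured.

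Gene families were scanned by symbol stem, over 379 stems with at least 6 tested members. Camera with a preset correlation called 27 of them and 0 with an estimated correlation (adjusted p = 0.991 for each family named here). The GIMAP genes led the scan, with 7 of 8 lower, 1 higher (GIMAP1-GIMAP5) and a median log2 fold change of -4.18 (adjusted p = 6.29e-29). GIMAP7 fell from 27.4 ± 2.92 to 0.517 ± 0.0423 CPM and GIMAP4 from 113 ± 2.74 to 6.68 ± 1.28 CPM. The clustered protocadherins fell in all 3 stems, with 10 of 12 PCDHB, 9 of 12 PCDHGA and 6 of 8 PCDHGB genes lower and none higher. PCDHGB7 went from 25.7 ± 1.98 to 2.16 ± 0.240 CPM. The PCDHB genes were below 2 CPM, 5 of them had no counts with MoNP-VP, and their median of -5.25 became -3.30 with these set to their bound. The PCDHG genes share their 3' exons, so reads can be split among them. Of 14 KLF genes, 9 rose and 1 fell (median 0.80, adjusted p = 0.00160). Of 12 genes with the stem SMG, 9 rose, and these include 6 pseudogenes of SMG1, led by SMG1P7 (2.47, SE 0.18), while SMG1 itself changed by 0.41 (SE 0.08). Reads of the pseudogenes cannot be cleanly separated from each other. The genes in this paragraph were chosen after their values were seen.

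The fall of the TNF and NF-kB list is the first pattern. Removing a trend of the fold change on transcript length and GC content, which explained 0.256% of its variance over 15554 genes, left the list's median at -1.68 (bootstrap 95% interval -2.18 to -1.01), and the rise of the ATF4 list at 1.60 (1.28 to 1.82). TNFRSF1A, the main TNF receptor gene, had a log2 fold change of -0.19 (SE 0.07, edgeR adjusted p = 0.0560), and -0.26 without MoNP-VP replicate 1. Among the settings that left out no library, TNFRSF1A was called lower with the filter at 5 CPM (0.0361), upper-quartile factors (0.0417) and copies summed (0.0477). The fall was larger, not smaller, without MoNP-VP replicate 1. In the main fit, the range of 2 SE for TNFRSF1A, -0.33 to -0.06, argues against a large fall of that gene only. TNFRSF1B, the other TNF receptor gene, was called lower (-1.403, SE 0.11, adjusted p = 7.54e-05), so lower receptor transcripts stay open. The 27 immediate early genes outside the list went both ways (11 higher, 11 lower, median 0.15, interval -0.92 to 0.60). That interval does not hold the list's median of -1.51, which argues against an even fall of all short-lived inducible transcripts. A fall of part of them stays open, since the 25th percentile was -1.36. The members' SD of 2.58 exceeded the distance of 1.66 to the list's median. By the criterion set for this test, a general fall was therefore left undecided. A lower response to TNF-alpha in cells given verteporfin remains a hypothesis, since the design has no cells without TNF-alpha, and toxicity of the cargo, receptor protein and timing were not measured.

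The fall of the endothelial identity list is the second pattern. After the same correction its median was -0.84 (-1.56 to -0.62). A lower share of endothelial cells, with all other cell types raised alike, would raise every other marker list. The fibroblast markers had a median of -2.36 (-3.85 to -1.47), smooth muscle and pericyte markers -0.05 (-0.64 to 1.10) and epithelial markers 0.69 (0.18 to 4.39). These medians argue against such an even shift only. A gain of a single other cell type stays open, since marker genes can also change by regulation within cells. The fibroblast test rests on the 10 of 15 markers detected in these cultures, the most abundant named ones being POSTN at 74.5 CPM and COL1A2 at 55.9 CPM with MoNP. No biological explanation of this fall was tested.

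The third pattern lies between the MoNP-VP libraries. Of 25 members of the TNF and NF-kB list, 23 were higher in MoNP-VP replicate 1 than in replicate 2, with a median log2 ratio of 0.34. That was above all of 10000 random lists matched on mean expression (95% between -0.03 and 0.08). Of 27 heat shock genes, 24 were not higher (median -0.22, below all 10000), and interferon-stimulated genes had a median of -0.00. The random lists hold unrelated genes, while the TNF and heat shock lists had an estimated correlation between members of 0.61 and 0.62. Any shift of a single library can put such lists outside the random ones, so these ranks do not measure how unusual the difference is. A first comparison left carry-over from a MoNP library undecided, since among genes that fell by at least 3 the excess in replicate 1 had a median of 0.776% of the MoNP level (0.265 to 1.22) for 40 genes outside the inflammatory lists and 1.22% (0.489 to 3.93) for 9 within them. Reads carried over would add the same share of the MoNP level to every gene. At the 5 abundant genes that fell furthest, the whole level left in replicate 1 was 0.585% (CX3CL1) to 1.51% (GIMAP8) of the MoNP level. CX3CL1 thus allows at most 0.585%, whereas the excess of the 23 lower members had a median of 7.88% (5.06 to 9.94) of their MoNP level. Carry-over within that limit stays open for the excess of CX3CL1 (0.489%) and VCAM1 (0.406%). The excess was larger for SELE (1.35%), CCL2 (3.93%) and ICAM1 (5.06%). Lists called higher with MoNP-VP did not go 1 way between these libraries, as the unfolded protein response had a median log2 ratio of 0.15 and the ATF4 list one of 0.07, and no biological explanation was tested.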
